A study of Homo sapiens with 2 samples.

How the data were processed

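Poly(A) RNA from a human corneal epithelial cell line was sequenced after culture in KSFM or in a serum-containing special medium, with RNA from 3 cultures pooled into 1 library per medium. Per the labels, the cells were cultured for 72 hours, RNA below a set integrity number was not used, and libraries were made with a stranded poly(A) kit. The submitters' processing notes name FastQC 0.11.9, fastp 0.20.0, HISAT2 2.1.0, RSEM and the GRCh38 build, without the order of the steps; the RSEM version, annotation release and strand setting are not given in the sources used here.

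The authors deposited 2 tables of 26506 genes by symbol. One holds estimated counts as the authors deposited them, fractional in 11.3% of genes in KSFM and 8.05% in the special medium, as probabilistic assignment of shared reads gives. The other holds TPM values as deposited, which sum to the same total in each library. An Ensembl identifier was missing for 4551 genes, and 21810 had a single match in GENCODE release 29 (GRCh38), which supplied coordinates and GC content. Mitochondrially encoded genes were not analysed here.

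Estimated counts were rounded to whole numbers, giving totals of 21604652 and 16900472. Library sizes were scaled by edgeR 4.0.16 TMM factors, 0.999 for KSFM and 1.00 for the special medium. For each gene the log2 ratio of special medium over KSFM was given an exact 95% Clopper-Pearson interval, conditional on the sum of the 2 counts. A count of 0 was set to 3 counts, which gives an approximate bound, and exact bounds, where given, lie lower. Sequencing reads without molecular identifiers are not independent molecules, so intervals and bounds cover counting error only. With 100 counts in each library the interval reaches about 0.41 to either side on the log2 scale, and with 1000 counts 0.13.

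There is no replicate spread and no test between conditions. A gene was called higher or lower when it had at least 1 CPM in either library, a ratio of at least 2-fold and an interval excluding equality. On Poisson simulations of this pair of libraries, with 200 genes changed, the rule called 100% of genes set at log2 ratios of 3, −3 and −1.5, 98.0% of those at 1.5, and 0.211% of 13256 unchanged genes. Such simulations hold no variation between cultures.

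Each gene list was summarised by its members at 1 CPM or more, how many passed the rule, and the percentile of its median log2 ratio among 10000 random lists of the same size drawn within 20 bins of mean expression. A list stood apart below the 2.5th or above the 97.5th percentile. Of 714 list entries fixed before the data were examined, 701 were found, 8 of them under older symbols; 10 further lists were added after the data were seen and are used in the closing section, apart from a count of liver markers and the median of small nucleolar RNA host genes.

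Genes named in the text are every membrane-associated mucin passing the filter; the 12 higher and 12 lower genes whose interval bound lies furthest from equality, among genes at 10 CPM or more with an established symbol; up to 4 members per list with the largest ratios past the rule, or the 2 most expressed if none passed; and other-cell-type markers at 10 CPM or more. Genes named outside this rule, as members below the filter, single exceptions in a list and comparators, were chosen after their values were seen. Some genes that the rule names are not reported here.

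Alternatives fixed before the data were examined were total count, DESeq2 1.42.0 and upper quartile scaling, TPM with pseudocounts of 1 and 0.1, a filter of 10 CPM or none, a 4-fold rule, an interval wholly beyond 2-fold, and random lists not matched on expression. Centring of the TPM ratios, and removal of a cubic trend of the ratios on effective length (estimated count per TPM) and GC content, were added after the data were seen. Effective length was taken for each gene from the library with the higher TPM, so it is not independent of the direction of the ratio. Computation used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.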

Results

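The series measured poly(A) RNA in human corneal epithelial cells, an established line of the human corneal surface epithelium (ATCC CRL-11515), grown for 72 hours in either of 2 media. The first was keratinocyte serum-free medium (KSFM), and the second, called the special medium in the labels, was DMEM/F12 with EGF at 10 ng/mL, calcium chloride at 1 mM, serum from fetal cattle at 10%, and antimicrobials. RNA from 3 independent cultures was pooled per medium before sequencing, so there is 1 library per condition, no replicate check of any difference, and no p-value. The KSFM library holds 21604652 counts over 26506 genes and the special medium library 16900472. Ratios are special medium over KSFM, and values in parentheses after a fold are exact 95% intervals that cover counting error only.

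The comparison asks, per the series title, how the medium changes expression of membrane-associated mucins, the transmembrane glycoproteins that form the glycocalyx of the ocular surface. All 4 membrane-associated mucins detected at 1 CPM (counts scaled to library size, the usual depth-normalised unit) or more were higher in the special medium. MUC1 was 11.5-fold higher (9.28 to 14.4), from 4.31 CPM in KSFM to 49.6 CPM, on 93 and 839 counts. MUC16, the largest of the ocular surface mucins, was 12.7-fold higher (8.60 to 19.5), from 1.30 to 16.5 CPM, on 28 and 279 counts. CPM does not adjust for transcript length, so it does not rank these genes by abundance. On the deposited TPM values MUC16 stayed below 1 in both media, at 0.05 and 0.77, against 0.56 and 14.2 for MUC20. MUC20 was 22.5-fold higher (12.9 to 42.8), from 0.602 to 13.5 CPM, and MUC4 was 4.72-fold higher (3.89 to 5.77), from 6.07 to 28.7 CPM.

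The median log2 ratio of these 4 genes was 3.60, against a middle 95% of −0.78 to 1.02 in 10000 random lists matched on expression. Of the other 7 listed mucins, MUC12, MUC15, MUC17, MUC21 and MUC22 had 0 counts in both libraries. The exact 95% upper limits of such counts are 0.171 CPM in KSFM and 0.218 CPM in the special medium. MUC3A had 1 and 0 counts and MUC13 had 1 and 3, so no difference was detectable at this depth. On GRCh38, in GENCODE release 29 gene bounds, MUC1 (ENSG00000185499) spans chromosome 1 from 155185824 to 155192916 and MUC16 (ENSG00000181143) chromosome 19 from 8848844 to 8981342. MUC20 (ENSG00000176945) and MUC4 (ENSG00000145113) are neighbours on chromosome 3, from 195720882 to 195741123 and from 195746765 to 195812277. Related duplicated sequence lies in that region, so the split of reads there is uncertain. Certainty of read assignment was not measured for any of the 4 mucins.

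**Figure D1:**
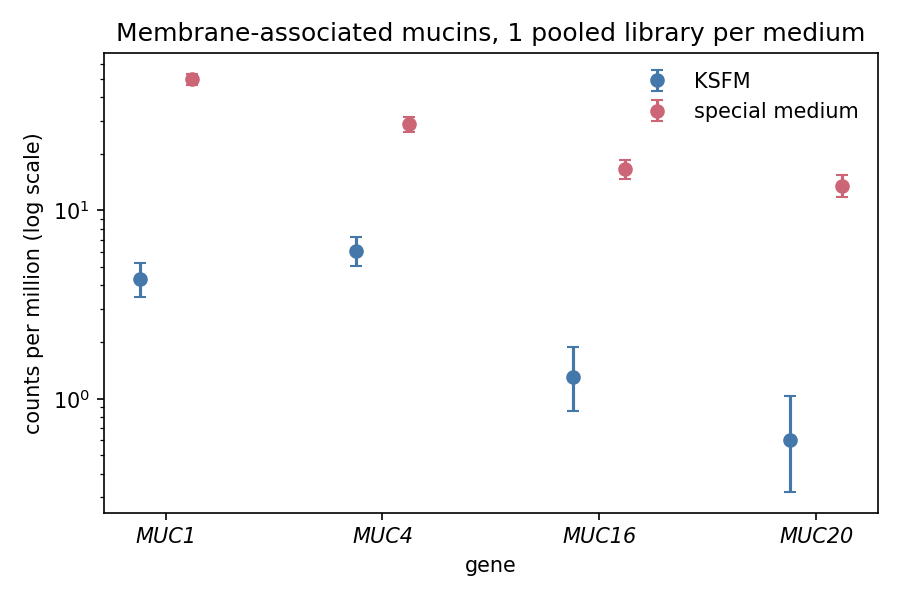
CPM (log axis) of the 4 membrane-associated mucins above the expression filter, with 1 point per medium (1 pooled library each) and bars for the exact 95% Poisson interval of the count. In each gene the special medium point lies above the KSFM point and the bars do not overlap, from 4.31 against 49.6 CPM in MUC1 to 0.602 against 13.5 CPM in MUC20.

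Across the 13632 genes at 1 CPM or more in either library, 1344 were at least 2-fold higher and 923 at least 2-fold lower in the special medium with an interval excluding equality, and 11365 were neither. By a 4-fold rule, 408 were higher and 162 lower. The middle 95% of log2 ratios ran from −1.53 to 2.21. Higher genes made up 59.3% of those past the 2-fold rule on counts, but 74.97% on the deposited TPM values with a pseudocount of 1 (1318 higher and 440 lower) and 71.4% with a pseudocount of 0.1 (1722 and 690). After centring of the TPM ratios (pseudocount 1) the share was 59.85% (951 and 638). The TPM scale shifts the median log2 ratio of all genes by 0.15 with the first pseudocount and by 0.16 with the second, so list medians on that scale are to be read against that shift.

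**Figure D2:**
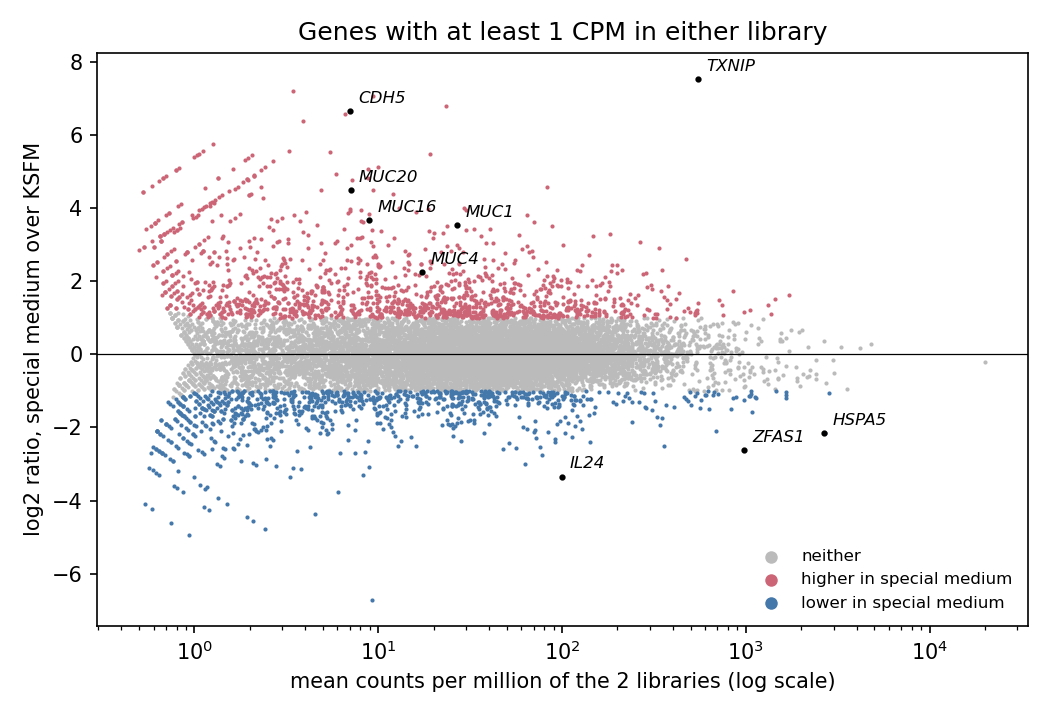
Log2 ratio of special medium over KSFM against the mean CPM of the libraries (log axis), 1 point per gene at 1 CPM or more in either library, coloured by the 2-fold rule. Genes with a count of 0 in a library are placed at the ratio given by 3 counts. The 4 labelled mucins lie between log2 ratios of 2.24 and 4.49, TXNIP lies highest at 7.53 and IL24 at −3.35.

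Among genes at 10 CPM or more, the one whose interval lay furthest above equality was TXNIP, a thioredoxin-binding arrestin-family protein that limits glucose uptake, which was 184-fold higher (155 to 221) in the special medium, from 5.89 to 1086 CPM. The serpin SERPINB3 was 111-fold higher (58.1 to 244), although it shares reads with its near-identical neighbour SERPINB4. ADGRF1, an adhesion G protein-coupled receptor, was 23.9-fold higher (20.2 to 28.5) and reached 158 CPM, and the interferon-induced GTPase GBP2 was 44.6-fold higher (28.0 to 75.8). The matrix Gla protein gene MGP was 34.9-fold higher, the GABA receptor subunit gene GABRP 33.5-fold, the niacin receptor gene HCAR2 28.3-fold, the ciliogenesis factor gene FOXJ1 45.9-fold and the antiviral gene OAS2 30.6-fold. TRIM31, a ubiquitin ligase gene with 0 counts in KSFM and 224 in the special medium, was at least 95.2-fold higher against the floor of 3 counts (exact 95% bound 76.8). HP, which encodes the plasma protein haptoglobin, had 0 and 315 counts and was at least 134-fold higher against that floor (exact bound 108), and 8 of 9 other liver-enriched transcripts, listed after HP was seen, were also past the 2-fold rule upward.

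Among genes lower in the special medium, IL24, a cytokine of the IL-10 family, was 10.2-fold lower (9.05 to 11.5), from 181 to 17.8 CPM. IL11, another cytokine gene, was 5.36-fold lower (4.72 to 6.11). Noncoding host genes of small nucleolar RNAs made up 3 of the 12 lower genes named by size: SNHG12 was 8.04-fold lower (7.03 to 9.23), SNHG8 6.70-fold (5.99 to 7.52) and ZFAS1 6.19-fold, the last from 1673 to 270 CPM. A list of such host genes, chosen after the data were seen, had a median log2 ratio of −1.53 over 20 genes, and −0.60 after correction for effective length and GC content, which covered 17 of them. The chaperone cofactor SDF2L1 was 6.07-fold lower, the signal peptidase subunit SEC11C 5.78-fold, the endoplasmic reticulum factor MANF 5.30-fold and the disulfide isomerase AGR2 5.23-fold. The uridine phosphorylase gene UPP1 was 5.66-fold lower (5.38 to 5.94), the arginase gene ARG2 5.93-fold (5.22 to 6.75), and DMBT1, a secreted mucosal scavenger receptor gene, 8.45-fold (5.88 to 12.6).

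Genes were also read as lists fixed before the data were examined, each by its median log2 ratio among random lists of the same size. Of 37 lists with members in the tables, 21 lay above the middle 95% of random lists, 7 below and 9 within, where chance would place about 1 in 20 outside. Members of a pathway vary together, so these percentiles describe the pair of libraries and are not evidence over cultures.

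**Figure D3:**
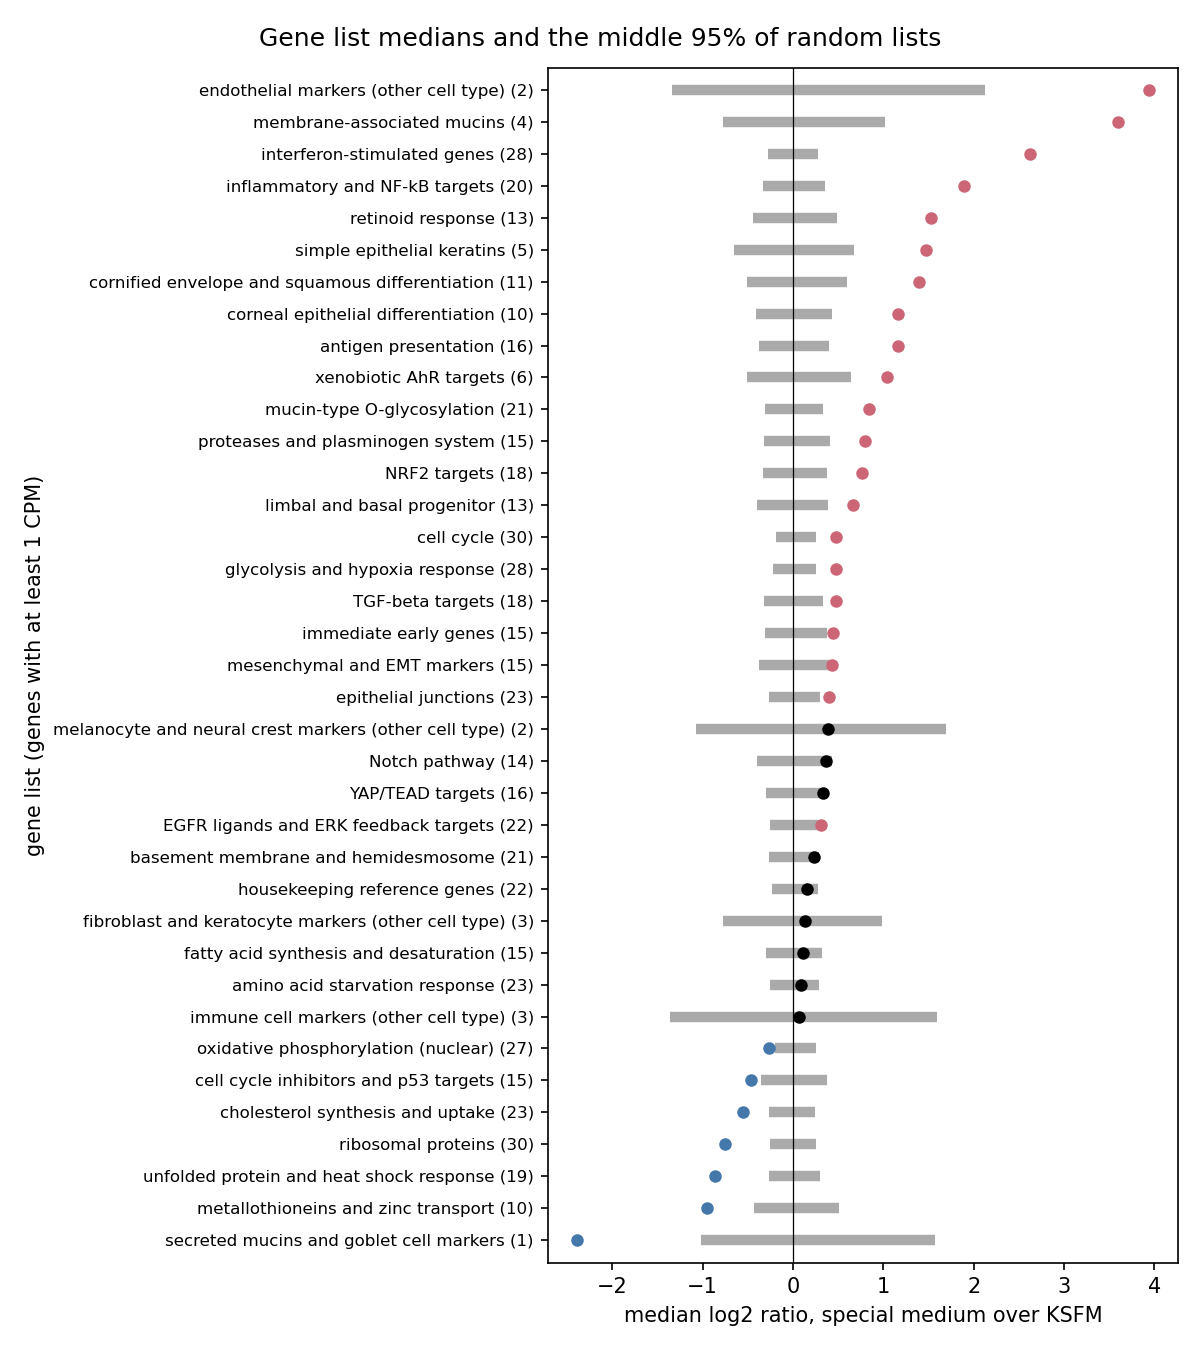
Median log2 ratio of special medium over KSFM for the 37 fixed gene lists (points; members above the expression filter in parentheses), with grey bars for the middle 95% of 10000 expression-matched random lists. Red points lie above the bar, blue points below and black points within it; the 4 mucins lie at 3.60 and the 28 interferon-stimulated genes at 2.63.

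In the list of mucin-type O-glycosylation, which builds the sugar chains of mucins, 10 of 21 measured genes were higher, 1 lower and 10 neither, and the median log2 ratio of 0.84 lay above the random range. The sialyltransferases ST6GALNAC1 and ST6GALNAC2, which add sialic acid to O-linked sugars, were 20.4-fold (7.59 to 77.2) and 5.07-fold (3.55 to 7.40) higher, and the chain-initiating enzymes GALNT5 and GALNT12 were 4.32-fold and 3.68-fold higher. ST6GALNAC4 was the gene past the rule downward, on 742 and 265 counts. The secreted mucins MUC2, MUC5AC, MUC5B, MUC6, MUC7 and MUC19 stayed below 1 CPM, and AGR2 was the only goblet cell marker measured, at a log2 ratio of −2.39; without the expression filter that list's median was 1.35.

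Epithelial gene lists were mostly higher in the special medium. Of 10 measured corneal differentiation genes 5 were higher and 0 lower (median 1.16), including the epithelial transcription factors ELF3 (9.82-fold, 9.09 to 10.6) and EHF (4.26-fold, 3.76 to 4.83), and transketolase, TKT (2.83-fold). The corneal keratins were scarcely detected, with KRT3 at 0 and 1 counts and KRT12 at 0 in both libraries. Simple epithelial keratins had 3 of 5 higher (median 1.48), with KRT23 3.74-fold, KRT19 3.43-fold and KRT8 2.78-fold higher. In the cornified envelope list 6 of 11 measured genes were higher and 1, KRT10, lower (median 1.39). That median was 0.76 on centred TPM with a pseudocount of 1 and 0.82 with a filter of 10 CPM, above the random range in both. CASP14, a protease of terminal keratinocyte differentiation, was 14.7-fold higher (10.8 to 20.5) and S100A9 6.87-fold (6.03 to 7.86). S100A8 and KRT13 each had 1 count in KSFM, so their ratios of 53.6 (9.10 to 2165) and 47.2 (7.96 to 1914) are poorly bounded. The other 23 members of that list, among them IVL at 5 and 8 counts and FLG at 0 and 3, were below 1 CPM in both media.

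Limbal and basal progenitor genes were 5 higher and 1 lower of 13 (median 0.66). ABCG2, a transporter used as a limbal stem cell marker, was 6.16-fold higher (4.48 to 8.62), KRT15 3.40-fold and SOX9 2.55-fold, while S100A2 was 3.63-fold lower. The mesenchymal list held 2 higher and 4 lower of 15: MMP2 was 8.26-fold (7.10 to 9.65) and CDH2 2.28-fold higher, and the transcription factor SNAI2 was 5.20-fold (4.38 to 6.21) and vimentin, VIM, 3.31-fold lower. That list's median of 0.43 lay just above the random range and was −0.09 without the expression filter.

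Cell junction genes were 6 higher and 1 lower of 23 (median 0.40), led by the tight junction genes CLDN4 (4.67-fold, 4.45 to 4.90), TJP3 (4.34-fold) and CLDN1 (3.81-fold), with the desmosomal cadherin DSC3 5.26-fold lower (2.36 to 13.8). Of 21 basement membrane and hemidesmosome genes 2 were higher, the integrins ITGB6 (6.59-fold) and ITGB4 (2.82-fold). The list median of 0.23 was within the random range, and above it after correction for effective length and GC content (0.40). Proteases and plasminogen system genes were 6 higher and 1 lower of 15 (median 0.79), with urokinase, PLAU, 6.08-fold (5.84 to 6.33), SERPINB2 8.21-fold, MMP1 5.25-fold and MMP13 4.34-fold (1.54 to 15.0) higher.

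Interferon-stimulated, inflammatory and antigen presentation genes were higher as lists. Of 28 measured interferon-stimulated genes 22 were higher and 0 lower in the special medium (median 2.63). IFI44L was 27.4-fold higher (15.0 to 55.6), the chemokine CXCL11 20.4-fold (7.59 to 77.2), and CXCL10, with 0 and 48 counts, at least 20.4-fold against the floor of 3 counts (exact bound 16.0). Inflammatory and NF-kB targets were 17 higher and 0 lower of 20 (median 1.89), with the neutrophil chemokine CXCL8 15.3-fold (12.2 to 19.5), SAA2 8.93-fold, the apoptosis inhibitor BIRC3 7.85-fold and IL1B 6.92-fold higher. SAA2 rested on 14 and 98 counts, and its TPM of 1.72 and 10.55 gives a smaller ratio. Certainty of its read assignment was not measured. Antigen presentation genes were 10 higher and 0 lower of 16 (median 1.16). These included TAPBP, which helps load peptide onto class I molecules, at 4.39-fold (4.02 to 4.79), the class I transactivator NLRC5 at 3.41-fold, and CD74 and CIITA, of class II presentation, at 5.58-fold and 5.38-fold from under 10 counts each.

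In the unfolded protein and heat shock list 7 of 19 genes were lower, 6 higher and 6 neither (median −0.86); the grouping by compartment that follows was made after the values were seen and was not tested. The 7 lower ones act in the endoplasmic reticulum: the chaperone HSPA5 was 4.45-fold lower (4.38 to 4.52), from 4352 to 978 CPM, and CRELD2 had a log2 ratio of −2.00, beside SDF2L1 and MANF. The 6 higher ones are heat shock genes of the cytosol, HSPA8, HSPA1A, HSPA1B, DNAJB1, HSPB1 and HSP90AA1, with log2 ratios from 1.18 in DNAJB1 to 1.92 in HSPA1B; HSPA1A and HSPA1B are near-identical copies. Amino acid starvation genes were within the random range (median 0.08), with TRIB3 2.41-fold lower and STC2 2.27-fold higher.

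Metallothioneins and zinc transport genes were 5 lower and 1 higher of 10 (median −0.95). The median was −0.58 after the length and GC correction and −0.56 with a filter of 10 CPM, below the random range in both. The metal-binding MT1X was 5.73-fold (4.54 to 7.32), MT2A 3.58-fold and MT1E 3.20-fold lower, with reads among these close paralogs uncertain, and the zinc importer SLC39A10 was 2.68-fold higher. NRF2 targets were 7 higher and 0 lower of 18 (median 0.76), including AKR1B10 (7.53-fold, 4.72 to 12.6), thioredoxin reductase TXNRD1 (3.34-fold) and NQO1 (2.89-fold). AhR targets were 3 higher of 6 (median 1.04): CYP1B1 (3.61-fold), AHRR (2.56-fold) and NQO1, which is counted in both lists. On TPM with a pseudocount of 1 the AhR median of 0.72 fell inside the random range.

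Of 23 cholesterol synthesis and uptake genes 6 were lower, 0 higher and 17 neither, with a list median of −0.55 below the random range. The sterol sensor partner INSIG1 was 2.56-fold lower (2.28 to 2.89), the sterol carrier STARD4 2.45-fold and DHCR7, the last enzyme of the pathway, 2.24-fold. Fatty acid synthesis genes were within the random range (median 0.12), with ELOVL6 and ACSS2 2.58-fold and 2.32-fold higher. Glycolysis and hypoxia genes were 8 higher and 0 lower of 28 (median 0.48), including EGLN3 (5.98-fold), CA9 (3.19-fold), ENO1 (3.07-fold, 3.02 to 3.12) and LDHA (2.65-fold).

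Ribosomal protein genes were 11 lower and 0 higher of 30 (median −0.76), with RPS19 2.76-fold (2.67 to 2.85), RPLP2 2.46-fold, RPLP1 2.38-fold and RPS27A 2.31-fold lower; these genes have many processed pseudogenes, which makes their counts less certain. The list stayed below the random range on TPM (−0.54) and after correction for length and GC content (−0.32). Nuclear genes of oxidative phosphorylation were 2 lower and 0 higher of 27 (median −0.26), NDUFA4 at 2.66-fold and COX5A at 2.23-fold. That median fell inside the random range on TPM (−0.02) and against unmatched random lists (−0.26), and turned to 0.04 after the correction.

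Retinoid response genes were 9 higher and 1 lower of 13 (median 1.52). The transglutaminase TGM2 was 8.33-fold (7.84 to 8.85), the retinaldehyde reductase DHRS3 7.88-fold (7.16 to 8.69) and RARRES3 7.32-fold higher, and the retinoic acid-binding CRABP1 was 4.08-fold lower (1.54 to 13.6) on 26 and 5 counts. TGF-beta targets were 4 higher of 18 (median 0.47), with ID1, a helix-loop-helix inhibitor also driven by BMP signals, 11.4-fold (10.1 to 12.8), TGFB2 5.64-fold, ID2 3.56-fold and LTBP3 2.21-fold higher. SMAD7, SKIL, PMEPA1 and TGFBI were among the 14 that were neither. EGFR ligands and ERK feedback targets were 3 higher of 22 (median 0.31; SPRY1 4.68-fold, EREG 2.85-fold and PHLDA1 2.19-fold), and immediate early genes 3 higher of 15 (median 0.44; NR4A2 4.16-fold, KLF2 3.70-fold and JUNB 2.20-fold). Both of these medians fell inside the random range with a filter of 10 CPM (0.29 and 0.41), and the first also against unmatched random lists (0.31).

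YAP/TEAD targets had 4 of 16 higher, led by tissue factor, F3, at 4.54-fold (4.32 to 4.76) and AJUBA at 2.89-fold; their median of 0.33 was within the random range on counts and above it on TPM with a pseudocount of 1 (0.49) and after the length and GC correction (0.52). Notch pathway genes had 4 of 14 higher, among them MFNG (4.30-fold) and HES1 (2.40-fold), with a median of 0.36 within the random range. Cell cycle genes were 4 higher and 0 lower of 30 (median 0.48), the mitotic kinases AURKA, PLK1 and CDK1 at 2.67-fold, 2.56-fold and 2.25-fold and BUB1B at 2.06-fold. Cell cycle inhibitors and p53 targets were 1 higher (FAS, 2.81-fold) and 1 lower (TP53INP1, 2.53-fold) of 15, with a median of −0.46 that fell inside the random range after the length and GC correction (−0.26). Housekeeping genes were within the random range (median 0.15), although PGK1 was 2.62-fold and TFRC 2.11-fold higher and EMC7 2.28-fold lower.

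Markers of other cell types were mostly scarce. In the endothelial list both measured genes were higher (median 3.94): the vascular cadherin CDH5 rested on 3 and 236 counts, a 100-fold ratio (33.9 to 490), and ROBO4 was 2.34-fold higher, while PECAM1 had 2 and 15 counts, VWF 6 and 2, KDR 10 in each and TEK 0. Without the expression filter that list's median of 0.79 was inside the random range, and on centred TPM with a pseudocount of 1 it was 1.74. Fibroblast, immune and melanocyte marker lists were within the random range, at medians of 0.14, 0.07 and 0.39. Of their genes, FAP was 3.55-fold higher (2.81 to 4.50), CD14 was 39.5-fold higher (10.5 to 334) on 2 and 62 counts and LYZ was 3.42-fold lower on 48 and 11. FBLN1 was at 115 and 111 CPM, CD68 at 57.0 and 59.8, and MITF at 18.6 and 21.3.

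With 1 pooled library per medium, a difference between cultures or library preparations cannot be separated from a difference between media. The labels give calcium, serum and EGF amounts for the special medium alone, so single components cannot be compared.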

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

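The length and GC correction and the centred TPM values were chosen after the data were seen. The mucin median log2 ratio stayed above the random range under every setting tried, between 3.13 and 4.01, against 3.60. On TPM, where genes needed 1 TPM in either library, that median covers MUC1, MUC4 and MUC20 only. MUC16 was left out there at 0.05 and 0.77 TPM, a log2 ratio of 0.75 with a pseudocount of 1, under 2-fold. The number of fixed lists standing apart stayed between 26 and 28, against 28. Of the ratios of named genes under the alternatives, 1147 stayed inside their main counting interval, 286 left it, and 0 of those past the 2-fold rule changed sign. No gene called higher in the main setting was called lower in another, or the reverse. Genes higher numbered 788 with a filter of 10 CPM, 837 with the whole interval beyond 2-fold and 408 by the 4-fold rule, against 1344; genes lower numbered 446, 395 and 162, against 923. These counts fall because fewer genes enter or a stricter rule is applied. Genes lower numbered 440 on TPM with a pseudocount of 1, and 588 after the length and GC correction; the former scale moves the median ratio up by 0.15, and centring it gave 951 higher and 638 lower. The correction also left out genes with no effective length or GC value (12434 of 13632 stayed); among those 12434 the uncorrected ratios gave 757 lower. Beyond these values the cause was not tested. Of the list medians that stood apart, 3 changed sign: secreted mucins and goblet cell markers (1.35) and mesenchymal markers (−0.0897) without the expression filter, which admits genes with few counts, and oxidative phosphorylation (0.0381) after the length and GC correction, which kept 23 of its 27 genes; the uncorrected median of those 23 was −0.30, at percentile 0.32. That list also fell inside the range of unmatched random lists, at percentile 3.25. Depth limits genes with few counts: 20 counts in each library leave the log2 ratio open by 0.97 to either side.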

Other observations

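Tests on length and GC content, centred TPM values, and all lists in this paragraph, were chosen after the data were seen, so the medians describe those lists and are not independent evidence. Besides the mucins, 9 of 10 measured genes of a mixed list of surface proteins and uroplakins were higher in the special medium (median log2 ratio 3.63). They include the urothelial plaque genes UPK2 (28.1-fold, 7.32 to 239, from 2 counts) and UPK1B (15.0-fold, 9.40 to 25.4). The list also holds TMPRSS protease genes and the receptor genes GABRP (33.5-fold) and ADGRF1 (23.9-fold), already named by size. It therefore does not stand for the glycocalyx. Guanylate-binding proteins were 5 higher of 6 (median 3.51; GBP4 20.7-fold, GBP1 10.6-fold). UDP-glucuronosyltransferases and aldehyde dehydrogenases were 4 higher of 5 (median 1.52), with UGT1A6 9.96-fold higher (7.98 to 12.6) and ALDH1A3 2.87-fold, to 2139 CPM. UGT1A6 was the only UDP-glucuronosyltransferase among the higher genes. ALDH1A3 is also in the retinoid list. Its log2 ratio of 1.52 is the median of both lists, so these medians are not separate results. ER translocation and signal peptide processing genes were 13 lower and 0 higher of 30 (median −0.93), with OSTC 3.92-fold, SEC61G 3.56-fold and SEC61B 3.28-fold lower. Complement and acute phase genes were 14 higher of 22 (median 2.41), among them CFI (22.7-fold, 13.9 to 39.4). That list also holds ALB, ORM1, HP and TF, the last 2 with its largest ratios. For HP and TF the next paragraph gives trace liver RNA as a possible explanation. With a filter of 10 CPM, which keeps HP and ALB and drops TF, the median was 1.89, so this value is not free of liver-enriched genes. Translation factors with a 5' TOP motif were within the random range (median −0.19). On centred TPM with a pseudocount of 1, which understates ratios of low genes, the medians were 2.35 for the surface protein and uroplakin list, 2.77 for the guanylate-binding proteins, 1.28 for the UDP-glucuronosyltransferase and aldehyde dehydrogenase list, −0.87 for ER translocation and 1.07 for complement and acute phase genes.

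The plasma protein genes call for a second look. Before their values were seen, 9 liver-enriched genes were listed: if liver cells or liver RNA had entered the special medium library, their median level should reach at least 10% of that of albumin, ALB, at 13.1 CPM. The median was 4.20 CPM and 8 of the 9 were past the 2-fold rule; all 8 had 0 counts in KSFM, so their median log2 ratio of at least 4.98 is a bound set by the floor of 3 counts. They include APOA1 at 0 and 110 counts, AMBP at 0 and 91, APOA2 at 0 and 82 and APOC3 at 0 and 78. Trace liver RNA in that library is a possible explanation for these genes and for HP and TF, but ALB had 18 counts in KSFM and 222 in the special medium, so KSFM held ALB reads while HP and the 4 genes given above had 0 there. Of other liver genes chosen after their values were seen, VTN had 2 and 65 counts, CES1 0 and 62, FGB 1 and 16, FGG 1 and 10, ADH1B 0 and 1, CYP2E1 2 and 12 and SERPINA1 612 and 550, while CRP, ARG1, AFP and HAMP had 0 in both. Transcription of these genes by the corneal cells in the special medium stays open and was not tested.

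Ribosomal protein and small nucleolar RNA host genes are short, and short transcripts were lower as a class: the 10% of genes with the lowest effective length had a median log2 ratio of −0.40 on counts, against 0.03 for the others, and −0.18 against 0.18 on TPM. Removing the trend on length and GC content brought the ribosomal protein median from −0.76 to −0.32, and that of 17 snoRNA host genes with the needed annotation from −1.56 to −0.60 (−1.53 uncorrected over all 20 measured, of which 11 were lower and 0 higher). Both stayed below the middle 95% of random lists, at −0.17 to 0.31 and −0.26 to 0.37. Effective length came from the library with the higher TPM, so short genes that were lower may be under-corrected. The trend may account for much of the size in both lists. Against random lists matched on effective length the margin of the ribosomal proteins was small (−0.76 against a lower bound of −0.69). For them these values cannot decide whether the trend is the whole cause. The snoRNA host genes lay well below that range (−1.53 against a lower bound of −0.69), which argues against effective length alone for this list. The snoRNA host genes are known substrates of nonsense-mediated decay, so a decay hypothesis was tested on 8 decay factors and feedback targets before their values were seen. Their median of −0.0941 lay at percentile 29.7, which decides neither way.

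For the number of genes that differ, a shift in scaling by a few very abundant genes was tested with total count scaling, which gave 2268 genes past the 2-fold rule against 2267 with TMM. A shift in scaling adds calls on 1 side and removes them on the other, so this sum hardly responds and cannot decide alone. Total count scaling gave 1351 higher and 917 lower, against 1344 and 923 with TMM. The TMM factors of 0.999 and 1.00 show only that these 2 scalings nearly coincided. Differences between cultures or libraries stay open, since each medium has 1 library.

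Hypotheses on the medium's components were written before the data were examined. Lipid from serum may lower sterol synthesis: the cholesterol list median of −0.55 lay below the 2.5th percentile of random lists, as this predicts. No prediction was written for the fatty acid synthesis list, which had 2 higher and 0 lower of 15 (median 0.12, within the random range). Retinoids in serum may act in the special medium: the retinoid list median of 1.52 lay at percentile 100, yet the direct targets CYP26A1 and RARB had 0 and 1, and 2 and 1 counts, and CYP26B1 had a log2 ratio of −0.37. For calcium-induced squamous differentiation, the cornified envelope median of 1.39 (0.76 on centred TPM with a pseudocount of 1) is in the predicted direction, but with 11 of 34 genes measured the list cannot speak for the programme as a whole. A further hypothesis, written after the interferon-stimulated genes were seen and before the interferon genes were, is that the cells may transcribe interferon in the special medium: IFNB1, IFNL1, IFNL2 and IFNL3 together had 2 and 24 counts, a log2 ratio of 3.94 (1.93 to 7.06), of which IFNL1 gave 2 and 20. IFNL1 was the 1 gene of the interferon list at 1 CPM or more, and its log2 ratio of 3.67 was within the random range (−3.35 to 4.81, percentile 91.3). None of these tests separates the components of the special medium.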
